A study of Mus musculus with 11 samples.

How the data were processed

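Ventricular RNA of 12 male mice of the TG1306/1R line was measured on 11 cDNA arrays with 2 colours. Per the labels, 25 µg of total RNA of each mouse was reverse transcribed with Cy3 or Cy5 nucleotides, and each array received the labelled cDNA of 2 mice. The slides carried a public mouse clone set and 1563 custom clones, printed with 32 pins, and control spots. The data used here are the table of log2 ratios of the 2 dyes that the authors deposited, with 1 value per spot and array. The scanner, the background correction and the normalization of these values are not given in the sources used here. The column medians lay between -0.0135 and 0.0037, so the arrays had been centred close to 0. The values ran from -3.64 to 5.12, which leaves open log2 and natural logarithms. They were taken as log2 values, and if they are natural logarithms every fold printed here is too small. Each of the 11 arrays had a value at 17207 of the 17664 spots. The spot brightness behind each ratio was not used here, so the depth per spot is unknown and precision is limited by the number of arrays.

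The ratio was taken as Cy5 over Cy3. No source used here states this, and the direction is therefore only likely. Its basis is that the labels say carrier hearts were chosen in part by the expression of hypertrophic markers, and that Nppb, measured among Nppa, Nppb, Acta1 and Myh7 as the only member, came out higher in both carrier groups (mean of both log2 changes 1.78). Agt, which this line overexpresses in the heart, also came out higher in both (2.09 and 2.15), and the opposite direction would make it lower in carriers. With the opposite direction every sign printed here would turn.

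The column of the array of WT1 and Hyp1 did not follow the spot order of the others. Its blocks were compared with the sum of the 2 other arrays of set 1, which estimates the same ratio. In 24 of 24 blocks the best match lay 8 blocks further on, with correlations of 0.527 to 0.744 against 0.222 for the highest of the other places, and the median correlation of blocks in their own place was 0.0534. Within a block, 40 of 46 groups of 12 positions followed this shift and 5 groups lay in their own place (correlations 0.680 to 0.971). The block correlations are over the 40 shifted groups alone. These groups were chosen by their correlations in the same data, so the height of the block correlations partly follows from that choice. Of 60 pairs of empty cells that could be compared, 49 lay at the same shift. The 11520 spots of the shifted groups were therefore moved back, which raised the correlation with the set 1 sum over named spots from 0.488 to 0.807, and 3840 spots (21.7% of the table) were left without a value on this array. This step was chosen after seeing the data, it was not part of the design fixed beforehand, and results with the column as deposited and with the array left out are given in the closing section. In 9 of the other arrays 31 or 32 of the 32 blocks matched best in their own place, but on the array of Dil1 and Hyp1, which is part of the sum, only 18 of 32 did. With this array or the array of WT1 and Dil1 alone in place of the sum, 24 of 24 blocks again matched best at the shift, over the same shifted groups.

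Spots were named through the platform annotation. Of the 17664 spots, 736 were control spots and were left out, 12563 had 1 gene symbol, 412 had several and 3953 were not listed and stay unnamed here. The gene identifiers of 12555 spots matched the mouse gene table and changed 0 symbols. Spots of a gene were averaged on each array. Spots that were not listed or had several symbols were kept as single features, and both are counted as unnamed. A feature needed a value on at least 9 of the 11 arrays. This left 12097 features, of which 8106 were genes and 3991 were unnamed spots, and 2851 of the genes had 2 or more spots.

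The ratios were fitted per feature by generalised least squares with terms for Hyp minus WT, Dil minus WT and the dye. Mice entered as random effects, since arrays of a set share mice. A ratio of mouse to residual variance shared by all features (0.303) was estimated by restricted maximum likelihood over features measured on all arrays. Residual degrees of freedom were those of ordinary least squares, which counts arrays and not mice. The fits were moderated with limma's eBayes (version 3.58.1, in R 4.3.3; prior degrees of freedom 3.26), and p-values were adjusted by Benjamini-Hochberg over all features with a threshold of 0.05. Errors of log2 changes are standard errors of this fit, with 4 mice per group. Because the variance ratio is shared by all features, they can understate the spread between mice for genes that vary more. Fhl1 in Dil minus Hyp, for example, has an error of 0.19 with values of 0.75, 0.34, 1.57 and 1.81 in sets 1 to 4. Because every array compares mice of the same set number, differences between sets cancel in each ratio. Genes were named by a rule fixed before the data were examined: for each comparison the 12 largest changes in each direction among passing genes with the same sign on every direct array, up to 4 passing members of each gene list, and Nppa, Nppb, Acta1, Myh7, Myh6, Agt, Atp2a2 and Notch1. With fewer than 5 such genes in a direction, the 5 with the smallest p were named. Members of a list named beyond this rule were picked after their values were seen and are marked as such.

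24 gene lists were also fixed before the data were examined, and 16 of them had at least 5 measured genes. These were tested with limma's cameraPR with a preset correlation between genes of 0.01, adjusted over 48 tests. With a correlation estimated from the arrays (limma's camera), 0 of the 20 list calls held, and the smallest adjusted p was 0.157. Counts of list members past the threshold are given over all features and adjusted over the list alone. The cardiac weight index of the groups was compared by exact permutation tests.

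The fit was tested on simulated data for the 12097 features with 67 features changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. These data were drawn from the model of the fit itself, with normal noise and the same ratio of mouse to residual variance for every feature. Each change was equal in all mice of a group. The recovered shares and false calls therefore do not test that model. For Hyp minus WT the fit recovered 80.6% of features changed by 0.5 and 98.5% of those changed by 1, with 11 false calls. For Dil minus WT the shares were 73.1% and 95.5% with 7 false calls, and for Dil minus Hyp 76.1% and 95.5% with 6 false calls. With the replicate number as a block the fit recovered 58.2%, 47.8% and 58.2% of features changed by 0.5 and 95.5%, 94.0% and 97.0% of those changed by 1 in the 3 comparisons, with 167 calls against 185 in Dil minus WT. The loss of calls with the block in the measured data, from 260 to 6 and from 20 to 0, is thus larger than in these simulations. The list test called a list of 20 genes moved by 0.3 in 20 of 20 simulations and made 3 calls in 960 tests of unmoved lists, but these simulations held no correlation between genes.

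The alternatives fixed beforehand were other centring and scaling of the arrays, no dye term, arrays as independent, direct arrays alone, the replicate number as a block, other limits on missing values, single spots in place of genes, robust eBayes, the Hyp3 sample with the second weight label as a separate mouse, a threshold of 0.1, and each set left out. Added after seeing the data were the WT1 and Hyp1 array as deposited, left out or with its last blocks also placed, named spots alone, and a dye term scaled to the control spots.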

Results

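Gene expression was compared in the ventricles of mice of the TG1306/1R line, which overexpresses angiotensinogen, the precursor of the vasoactive peptide angiotensin II, in the heart. The 12 males were about 60 weeks old and formed 3 groups of 4, namely littermates without the transgene (WT), heterozygous carriers with concentric hypertrophy (Hyp) and heterozygous carriers with a dilated heart (Dil). The mice are numbered from 1 to 4 in each group, and mice with the same number are called a set here. Each of the 11 arrays compared 2 mice of a set: 4 arrays compared WT with Hyp, 3 compared WT with Dil and 4 compared Hyp with Dil. The WT and Dil array of set 2 was not analysed here. Each array gave a ratio at 17207 of 17664 spots, and 12097 features were tested, of which 8106 were named genes.

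The cardiac weight index (heart weight over body weight) was 4.53 ± 0.287 mg/g in WT, 5.54 ± 0.180 mg/g in Hyp and 8.23 ± 0.665 mg/g in Dil (SD, n = 4 each). Each pair of groups was fully separated (two-sided exact permutation p = 0.0286, adjusted p = 0.0286, the smallest value that 4 against 4 allows). Hyp3 carries 2 label values, 5.3 and 5.6 mg/g, whose mean was used, and either value alone gave the same p. Hearts were assigned to the carrier groups partly by this index and by hypertrophic marker expression, so both describe the groups and are not independent outcomes.

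Dilated hearts were compared with WT hearts to find genes that accompany dilatation. Dil hearts had higher Nppb, which codes for the secreted B-type natriuretic peptide, by 2.53 ± 0.32 on the log2 scale (5.79-fold, SE, 4 mice per group, adjusted p = 0.00866, higher on 3 of 3 direct arrays). Agt, the angiotensinogen gene, rose by 2.15 ± 0.40 (4.44-fold, adjusted p = 0.0311), and whether its spot (a second Agt spot has no value on any array) reads the transgene's transcript, the endogenous transcript or both was not tested. Rcan1, a calcineurin inhibitor, rose by 1.56 ± 0.13 (2.95-fold, adjusted p = 0.00102). The carboxylesterase gene Ces1d fell most among the named genes (-2.37 ± 0.28, adjusted p = 0.00685). Over all features 260 passed the test, 121 higher and 139 lower in Dil, and 206 of them were named genes (100 higher, 106 lower).

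Among the other genes with the largest rises in Dil hearts were Tgfb2, a transforming growth factor (1.36 ± 0.23), Fhl1, a LIM-domain protein of muscle (1.26 ± 0.20), the metallothionein Mt2 (1.20 ± 0.18), the transglutaminase Tgm2 (1.10 ± 0.17), Fxyd6 (1.10 ± 0.19), the glycogen-targeting phosphatase subunit Ppp1r3c (1.08 ± 0.18) and the secreted Wnt-binding protein Sfrp1 (1.06 ± 0.21). Efhd2 (1.04 ± 0.22) and Amot (1.03 ± 0.13) completed the 12 largest. On the lower side were Lgals4 (-1.35 ± 0.17), Ces1f (-1.28 ± 0.18), the lipid transfer protein Stard10 (-1.11 ± 0.12), the pyruvate dehydrogenase phosphatase Pdp2 (-1.11 ± 0.21), Hrc, a calcium-binding protein of the sarcoplasmic reticulum (-1.08 ± 0.14), and Ech1, an enzyme of fatty acid oxidation (-0.96 ± 0.14). Phkg1 (-0.93 ± 0.14), Rgs2, a regulator of G protein signalling (-0.93 ± 0.13), Dgat2, an enzyme of triglyceride synthesis (-0.90 ± 0.20), Ppip5k2 (-0.88 ± 0.13) and Fbp2 (-0.85 ± 0.17) followed. All of these had the same sign on the 3 direct arrays, as the naming rule required, with adjusted p from 0.00369 for Stard10 to 0.0486 for Dgat2. Of all 260 passing features, 248 had the same sign on their direct arrays.

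Genes of mitochondrial energy metabolism were lower in Dil than in WT hearts. Of 29 measured genes of fatty acid oxidation, 8 fell and 0 rose over all features, 14 fell adjusted over the list alone, and 28 had values below 0 (median -0.37). Examples are Ech1, Decr1 (-0.76 ± 0.16), Hadh (-0.73 ± 0.15) and Acot2 (-0.70 ± 0.16). Of 20 genes of the TCA cycle and pyruvate dehydrogenase, all 20 lay below 0 (median -0.26), 3 fell over all features, namely Suclg1 (-0.52 ± 0.11), Fh1 (-0.46 ± 0.09) and Mdh2 (-0.32 ± 0.07), and 13 fell adjusted over the list alone. Of 64 genes of oxidative phosphorylation, 12 fell, 41 fell adjusted over the list alone and 61 lay below 0 (median -0.33), with Cox6c (-0.63 ± 0.15), Ndufa13 (-0.57 ± 0.09), Cox6b2 (-0.53 ± 0.10) and Ndufb11 (-0.51 ± 0.11) as examples. The adjusted p of the 3 lists in cameraPR was 4.27e-15, 1.52e-11 and 6.27e-25, and with an estimated correlation the adjusted p was 0.233, 0.233 and 0.157. The fatty acid oxidation median was -0.28, -0.22, -0.64 and -0.52 in sets 1 to 4. For the TCA cycle it was -0.16, -0.13, -0.38 and -0.41, so both lists fell more in sets 3 and 4. On the direct arrays the oxidative phosphorylation median was -0.05 and -0.13 in sets 1 and 3, with Dil in Cy5, and -0.70 in set 4, the only one with Dil in Cy3, so here dye and mice are confounded.

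Genes of the extracellular matrix were higher in Dil hearts (median 0.35, 26 of 29 above 0, cameraPR adjusted p = 5.55e-10, adjusted p = 0.243 with an estimated correlation). Of these, 3 rose over all features, namely Tgfb2, Fstl1 (0.70 ± 0.14) and the basement membrane collagen gene Col4a1 (0.62 ± 0.14), and 12 rose adjusted over the list alone. The list median was 0.02 and 0.13 in sets 1 and 2 against 0.54 and 0.68 in sets 3 and 4. The fibroblast markers, which share collagen genes with this list, moved with it by set (-0.19, -0.01, 0.29 and 0.24). Ratios of all spots were also wider on the WT and Dil arrays of sets 3 and 4 than on that of set 1. Their scaled median absolute deviations were 0.335 and 0.354 against 0.172, control spots left out. Cell cycle genes had a median of 0.16 (adjusted p = 0.000436, adjusted p = 0.243 with an estimated correlation), with 0.01, -0.02, 0.25 and 0.29 in sets 1 to 4, and Ccnd2, a D-type cyclin, was the only member that rose over all features (0.61 ± 0.08, 2 adjusted over the list alone). Chaperone and unfolded protein response genes had a median of 0.15 (adjusted p = 0.00233, adjusted p = 0.5001 with an estimated correlation), with Hsp90aa1 (0.74 ± 0.15) and Hspa4 (0.45 ± 0.10) higher over all features and, adjusted over the list alone, 3 higher and 1 lower.

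Among the other lists, that of hypertrophic markers was too short to test. All 3 measured markers rose (Nppb, Rcan1 and Fhl1, also adjusted over the list alone), which is not independent of how the hearts were chosen. The lists that follow did not pass as lists in Dil against WT. Among 14 genes of calcium handling and excitability, Hrc and the potassium channel gene Kcnd2 (-0.62 ± 0.12) fell and Atp1b1, a sodium pump subunit, rose (0.40 ± 0.09), while the list had an adjusted p of 0.0524 (median -0.05). Adjusted over the list alone, 3 of these 14 fell and 1 rose. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at -0.47 ± 0.16 (adjusted p = 0.169). Its values were -0.02, -0.03, -0.86 and -0.65 in sets 1 to 4. Among 17 glycolysis genes, Pfkp, a phosphofructokinase, rose (0.96 ± 0.18) and the muscle enolase Eno3 fell (-0.60 ± 0.13), with 5 higher and 2 lower adjusted over the list alone (median 0.01, list adjusted p = 0.272). Eno3 had the fitted sign on only 2 of 3 direct arrays. Among 32 genes of the proteasome and muscle ubiquitin ligases the activator gene Psme1 fell (-0.67 ± 0.09), with 1 lower and 1 higher adjusted over the list alone (list adjusted p = 0.706). Notch1 was at 0.25 ± 0.21 (adjusted p = 0.628), and 0 of 21 Notch pathway genes passed, also adjusted over the list alone (list adjusted p = 0.3997). Of 16 antioxidant genes Mt2 passed (2 higher and 2 lower adjusted over the list alone, list adjusted p = 0.329). The sarcomere (median 0.19, adjusted p = 0.142), creatine kinase and adenylate transfer (-0.11, adjusted p = 0.796) and cytosolic ribosomal protein lists (-0.01, adjusted p = 0.796) held 0 passing genes over all features and, adjusted over the list alone, 1 higher, 3 higher with 1 lower, and 0.

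Markers of other cell types were measured as well. The median was -0.06 for 7 endothelial and 0.11 for 10 fibroblast markers in Dil minus WT (adjusted p = 0.724 and 0.272, 0 passing over all features, 1 fibroblast marker higher adjusted over the list alone). Lists of smooth muscle (4 measured, median -0.24), adipocyte (4, -0.01), macrophage and leukocyte (3, 0.19), erythrocyte (2, 0.22) and lymphocyte markers (1, 0.20) were too short to test, and 0 of their genes passed over all features, while 2 smooth muscle genes were lower and 1 erythrocyte gene higher adjusted over the list alone. The atrial list had 0 measured genes, and the renin-angiotensin list had 2, Agt and Agtr2. Nppa, Acta1, Myh7 and Myh6 were not measured here.

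With the replicate number as a block, 6 features passed in Dil minus WT, all among the 260: Agt, Rcan1, Ppp1r3c, Lgals4, Ces1f and an unnamed spot. Of these, the call of Agt ended without any 1 of the 4 sets (adjusted p = 0.0818, 0.0862, 0.199 and 0.203), with arrays scaled to the same spread (0.106) and with the WT1 and Hyp1 array as deposited (0.0804), and held with that array left out (0.0422). The call of Ppp1r3c ended without set 2, 3 or 4 (adjusted p = 0.0607, 0.250 and 0.0916), with arrays scaled to the same spread (0.0992) and from direct arrays (0.0639), and those of Ces1f and Lgals4 from direct arrays (0.0639 each). Without set 3 the calls of Rcan1, Lgals4 and Ces1f ended as well (0.199, 0.232 and 0.254). The count also rested on few mice: it was 0 without set 3, 12 without set 4, 80 without set 2 and 121 without set 1, and 7 from the direct arrays alone.

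**Figure D1:**
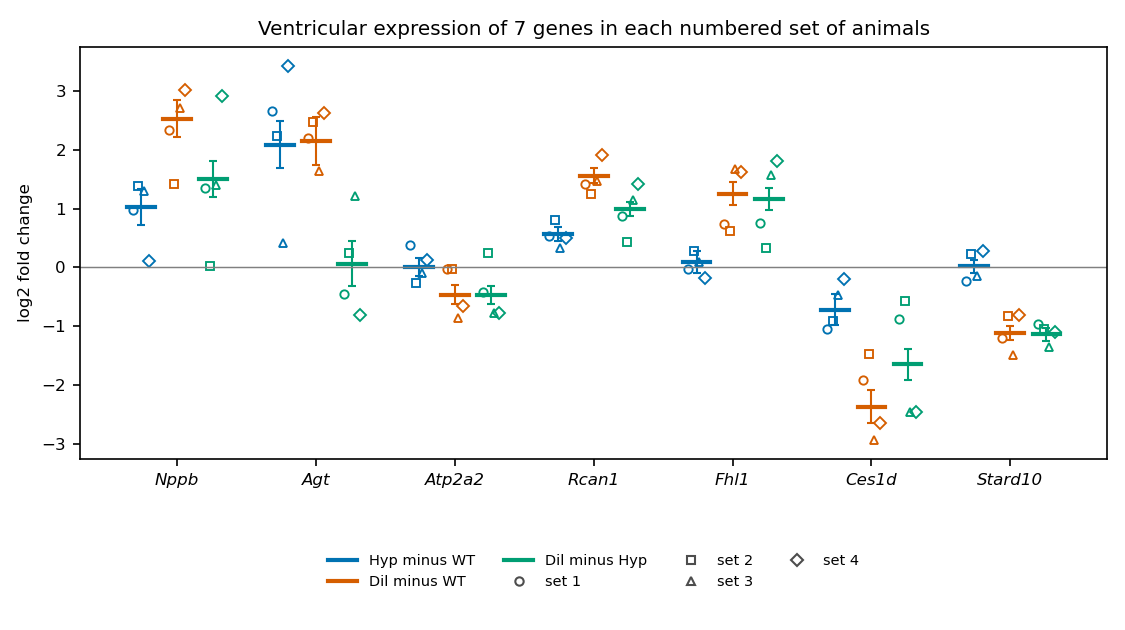
Log2 fold change (vertical axis) of 7 genes in the 3 comparisons, with the fitted change (bars) and its standard error, and the values of the 4 sets as open symbols. Nppb and Rcan1 lie above 0 in all 4 sets of Dil minus WT, and Agt in set 3 of Hyp minus WT is at 0.41.

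Hypertrophic hearts were compared with WT hearts to find genes that accompany hypertrophy without dilatation. Genes of chaperones and the unfolded protein response, which fold and quality-check proteins, were higher in Hyp hearts (median 0.38, 17 of 19 above 0, cameraPR adjusted p = 4.78e-17, adjusted p = 0.157 with an estimated correlation), mostly in sets 1 and 2 (set medians 0.36, 0.70, 0.14 and 0.07). Genes of fatty acid oxidation were lower (median -0.22, 27 of 29 below 0, adjusted p = 1.92e-13, adjusted p = 0.233 with an estimated correlation). No single feature passed limma's test over all features: 0 of 12097, with 533 at an unadjusted p under 0.05 where chance gives 605, and a smallest adjusted p of 0.871. The replicate block, too, gave 0.

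Adjusted over the list alone, 8 of the 19 chaperone genes rose, 2 fatty acid oxidation genes fell and the only Notch pathway gene to rise was Hes1 (0.59 ± 0.14). Picked after their values were seen, the chaperone genes include Xbp1, a transcription factor of the unfolded protein response (0.73 ± 0.16), the calcium-binding chaperones Calr (0.68 ± 0.25) and Canx (0.41 ± 0.10), the protein disulfide isomerase Pdia4 (0.51 ± 0.13) and Hspa5, the main heat shock protein of the endoplasmic reticulum (0.38 ± 0.11). The fatty acid oxidation genes were the carnitine palmitoyltransferase Cpt1a (-0.46 ± 0.11) and the carnitine carrier Slc25a20 (-0.35 ± 0.08). In cell cycle genes 2 rose adjusted over the list alone while the list did not pass (adjusted p = 0.0754). Of the hypertrophic markers, Nppb was at 1.02 ± 0.30 and Rcan1 at 0.57 ± 0.12, and these 2 of 3 passed adjusted over the list alone. Agt had a change of 2.09 ± 0.40 (4.26-fold, adjusted p = 0.871), with 2.65, 2.24, 0.41 and 3.43 in sets 1 to 4, and passed adjusted over its list of 2. Atp2a2 was at 0.00 ± 0.15 and Notch1 at 0.45 ± 0.20 (adjusted p = 0.999 each).

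The genes with the smallest p in Hyp minus WT, none of which passed, were Dnajc3, a chaperone of the endoplasmic reticulum (0.62 ± 0.11), Agt, Mpdu1 (0.34 ± 0.07), Xbp1 and the stress response regulator Nfe2l2 (0.45 ± 0.10) on the higher side. On the lower side they were Tesc (-0.43 ± 0.07), the peroxisomal transporter Abcd3 (-0.37 ± 0.08), Chkb, a choline kinase (-0.29 ± 0.06), Gpcpd1 (-0.47 ± 0.11) and the laminin gene Lamb3 (-0.50 ± 0.12).

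Further lists passed cameraPR in Hyp minus WT with smaller medians. Genes of the TCA cycle (-0.10, adjusted p = 1.22e-05) and of oxidative phosphorylation (-0.11, adjusted p = 6.02e-09) were lower, both with an adjusted p of 0.243 with an estimated correlation. On the 2 direct arrays with Hyp in Cy5 the oxidative phosphorylation median was 0.03, and on those with Hyp in Cy3 it was -0.20. For the TCA cycle these medians were -0.03 ± 0.04 (8 of 20 above 0) and -0.19 ± 0.02, with errors over genes and not over mice. Genes of the proteasome and muscle ubiquitin ligases were lower (-0.05, adjusted p = 0.00233, adjusted p = 0.437 with an estimated correlation), a call that ended without set 1 (adjusted p = 0.567). Notch pathway genes were higher (0.11, adjusted p = 0.00984, adjusted p = 0.243 with an estimated correlation), with 0.18 on direct arrays with Hyp in Cy5 and -0.05 on the others, and the call ended without set 1 (adjusted p = 0.523), without set 4 (0.116), without a dye term (0.185) and with arrays scaled to the same spread (0.107). Extracellular matrix genes were at 0.11 (adjusted p = 0.0487, adjusted p = 0.735 with an estimated correlation). This call ended in 8 of 20 alternatives, among them those without set 2 (adjusted p = 0.376) and without set 3 (adjusted p = 0.239). Endothelial and fibroblast markers had medians of -0.02 and -0.01 (adjusted p = 0.763 and 0.868).

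**Figure D2:**
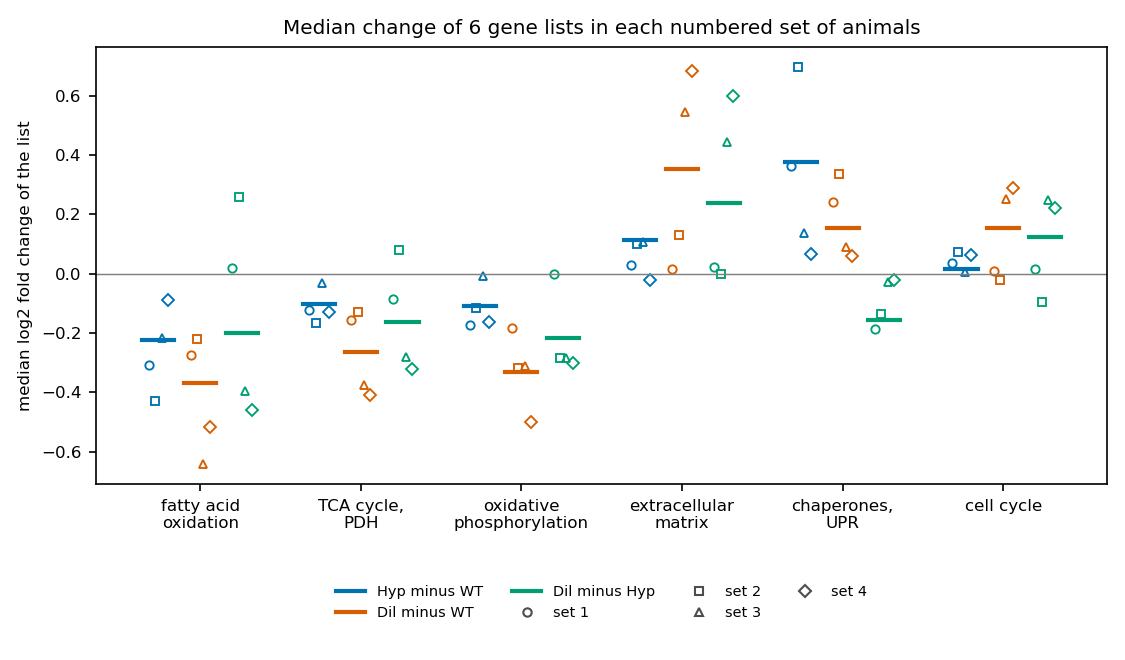
Median log2 fold change (vertical axis) of 6 gene lists in the 3 comparisons, over all mice (bars) and in each of the 4 sets (open symbols). The extracellular matrix median of Dil minus WT is 0.02 and 0.13 in sets 1 and 2 and 0.54 and 0.68 in sets 3 and 4.

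Dilated and hypertrophic hearts, both of carriers, were compared to find what sets the phenotypes apart. Fhl1 (1.16 ± 0.19, 2.24-fold), Rcan1 (1.00 ± 0.12, 2.00-fold) and Amot (0.97 ± 0.13) were higher in Dil, and Ces1d (-1.65 ± 0.26), Stard10 (-1.13 ± 0.11) and the growth factor gene Igf2 (-0.56 ± 0.09) were lower (adjusted p from 0.00522 for Stard10 to 0.0397 for Fhl1, same sign on all 4 direct arrays). In all, 20 features passed, 17 higher and 3 lower in Dil, of which 18 were genes. All 20 had the same sign on their direct arrays, which the naming rule required of the named genes. The others named on the higher side were Otulin (0.85 ± 0.13), Uck2 (0.80 ± 0.12), Sorbs2 (0.67 ± 0.11), Prnp (0.67 ± 0.10), the kinesin Kif5b (0.66 ± 0.08), Camta1 (0.58 ± 0.09), Nabp1 (0.55 ± 0.07), Aopep (0.52 ± 0.08) and talin, Tln1 (0.49 ± 0.08). Rgs2 (-0.71 ± 0.12, adjusted p = 0.0520) and Ech1 (-0.77 ± 0.14, adjusted p = 0.0558) did not pass, nor did Nppb (1.51 ± 0.30, adjusted p = 0.0845). Agt differed by 0.06 ± 0.38 (adjusted p = 0.987), Atp2a2 by -0.47 ± 0.15 (adjusted p = 0.303) and Notch1 by -0.21 ± 0.20 (adjusted p = 0.872).

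Mitochondrial lists were lower in Dil than in Hyp hearts too. The median was -0.22 for oxidative phosphorylation (59 of 64 below 0, 8 fell adjusted over the list alone), -0.16 for the TCA cycle (20 of 20 below 0) and -0.20 for fatty acid oxidation (24 of 29, 1 fell adjusted over the list alone), with 0 members passing over all features. Sets differed, with -0.09, 0.08, -0.28 and -0.32 for the TCA cycle and 0.02, 0.26, -0.39 and -0.46 for fatty acid oxidation in sets 1 to 4. Their adjusted p was 8.09e-19, 1.02e-07 and 1.22e-05, and with an estimated correlation the adjusted p was 0.157, 0.243 and 0.440. Extracellular matrix (0.24, 11 rose adjusted over the list alone), cell cycle (0.12, 1 rose) and the 5 measured sarcomere genes (0.31, 1 rose) were higher, with adjusted p of 1.34e-10, 0.00220 and 0.0155 and an adjusted p of 0.243 each with an estimated correlation. By set, the matrix median was 0.02, -0.00, 0.44 and 0.60 and the cell cycle median 0.01, -0.10, 0.25 and 0.22, so both rises lay in sets 3 and 4. Ratios of all spots were wider as well on the Hyp and Dil arrays of sets 3 and 4. Their scaled median absolute deviations were 0.236 and 0.250, against 0.127 and 0.169 in sets 1 and 2, control spots left out. Chaperone genes were lower in Dil (-0.16, adjusted p = 0.0411, adjusted p = 0.4998 with an estimated correlation), but 1 rose adjusted over the list alone, and the call ended without set 1 (adjusted p = 0.619) or set 2 (0.385), with Hyp3 as 2 mice (0.0643), and with the WT1 and Hyp1 array as deposited (0.245) or left out (0.0791). It thus rests on the reordering of that array, which was chosen after seeing the data. The list medians of endothelial and fibroblast markers were 0.00 and 0.05 (adjusted p = 0.796 and 0.164), and those of fibroblast markers by set were -0.01, -0.24, 0.25 and 0.38. Of the lists too short to test, the 2 erythrocyte markers were higher in Dil (median 0.39, 2 adjusted over the list alone, 0.47, 0.43, 0.30 and 0.31 by set), and the 4 smooth muscle markers had a median of -0.28 (4 of 4 below 0, 2 lower adjusted over the list alone).

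With the replicate number as a block, 0 features passed in Dil minus Hyp (limma, against 1166 at an unadjusted p under 0.05 in the fit without it), and direct arrays alone also gave 0. The count was 0 without set 1, 3 or 4 and 15 without set 2, and the call of the cell cycle list (adjusted p = 0.137) and of the sarcomere list (adjusted p = 0.114) ended without set 4, the latter also from direct arrays alone (adjusted p = 0.122).

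The changes of the carrier groups against WT were set side by side. Both comparisons share the WT mice: the correlation over features was 0.684 against 0.532 in simulations without effects (highest of 20, 0.554), and the covariance was 0.0169 against 0.00628. With Hyp and Dil values taken from different sets the correlation was 0.329 and 0.367. All 20 features passing in Dil minus Hyp, 17 higher and 3 lower, were among those passing in Dil minus WT, where independent lists would share 0.170 and 0.0345, a value that leaves out the shared Dil mice.

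**Figure D3:**
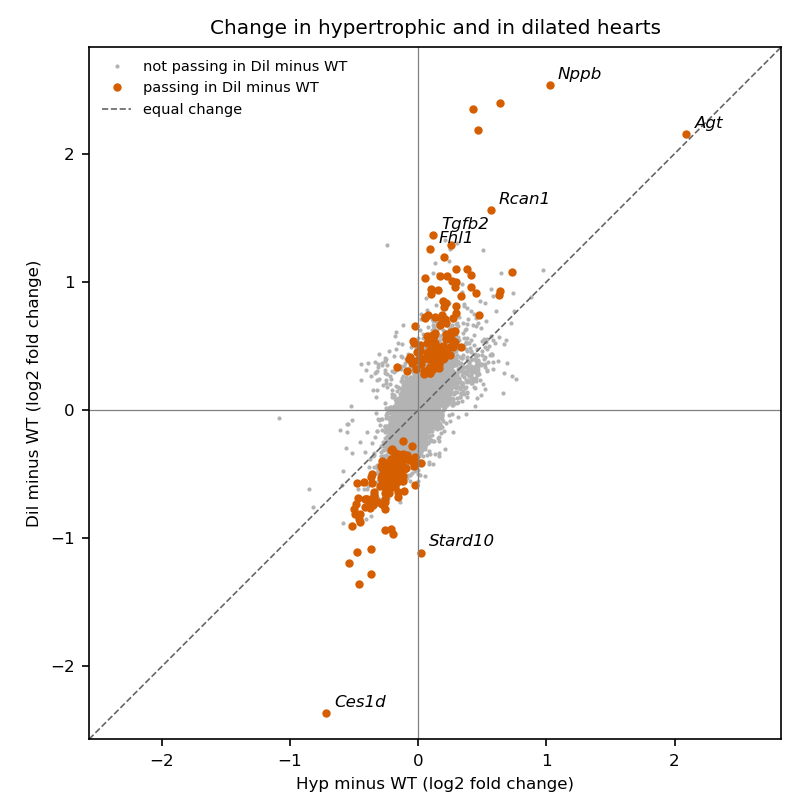
Log2 fold change of each of 12097 features in Hyp minus WT (horizontal axis) and Dil minus WT (vertical axis), with the 260 features that passed in Dil minus WT in orange and a dashed line of equal change. Agt lies near the line, at 2.09 and 2.15, and Nppb far above it, at 1.02 and 2.53.

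**Figure D4:**
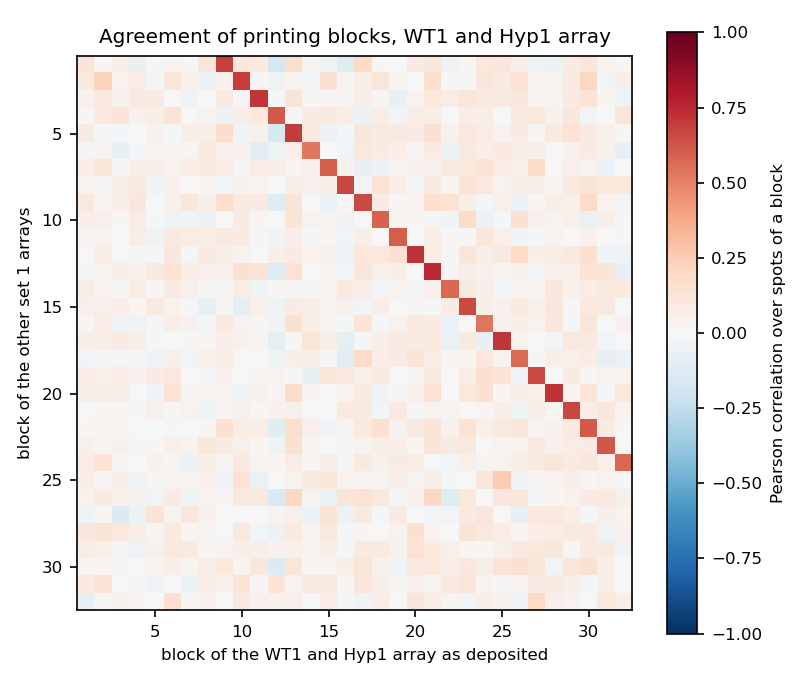
Pearson correlation between printing blocks of the WT1 and Hyp1 array as deposited (horizontal axis, 32 blocks) and blocks of the sum of the other set 1 arrays (vertical axis), over named spots. Only groups of positions that follow the shift are included. The high values lie 8 blocks to the right of the diagonal, at 0.527 to 0.744 in 24 blocks.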

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

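The tests of this part were chosen after the results were seen, except for the counts of splits, which were planned.

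With 4 numbered pairs there are 8 ways to swap groups within sets, too few for a share under 0.05. In Hyp minus WT all 8 splits, the real one included, gave 0 features past the threshold. In Dil minus WT 1 of the 8 splits, the real one, gave as many features (260, highest other 0), and in Dil minus Hyp also 1 (20, highest other 2). For gene lists, as many calls came from 1 split in Hyp minus WT (7, highest other 6), from 4 in Dil minus WT (6, highest other 9) and from 4 in Dil minus Hyp (7, highest other 10). The list calls at the preset correlation are therefore no firmer than these counts. In Hyp minus WT the split that swaps sets 2 and 3 coincides with the dye orientation, and it had 2194 features at an unadjusted p under 0.05 against 533 in the real split. This points to a structure of the samples: set correlations of Hyp minus WT were 0.403 (sets 1 and 4, Hyp in Cy5) and 0.419 (sets 2 and 3, Hyp in Cy3) within an orientation and -0.321 to -0.109 across. The other comparisons did not follow the dye. Dil minus Hyp gave -0.150 and 0.155 within an orientation and -0.293, 0.00970, 0.264 and 0.574 across, the last for sets 3 and 4. Dil minus WT gave 0.143 within Cy5 against 0.359 and 0.385 across. The dye term of the fit passed the threshold for 554 of 12097 features (377 higher in Cy5), so dye effects are common. The set values behind these correlations had a dye effect common to all arrays removed, and sets 3 and 4 still gave -0.316 in Hyp minus WT. Whether dye effects that differ between arrays, or the mice, lie behind this split was not tested.

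Chaperone and unfolded protein response genes were higher in Hyp than in WT hearts. A dye bias of these genes needs opposite signs in the 2 orientations, but the list median was 0.295 ± 0.0867 with Hyp in Cy5 and 0.337 ± 0.109 with Hyp in Cy3. These errors are over genes, and single arrays differed, with 0.51 and -0.02 in sets 1 and 4 and 0.63 and 0.08 in sets 2 and 3. More fibroblasts in Hyp hearts would raise their markers as much, yet the upper quartile of these markers was 0.0591. Other cell types were covered thinly. In Hyp minus WT the median was -0.02 for 7 endothelial and 0.11 for 3 macrophage and leukocyte markers. The only measured lymphocyte marker was at 0.22. No biological explanation was tested.

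Oxidative phosphorylation genes were lower in Dil than in WT hearts. A smaller share of cardiomyocytes would lower sarcomere genes alike. The lower quartile of the 5 measured, of 22 listed, was 0.0754 against an oxidative phosphorylation median of -0.33. Of 14 calcium handling and excitability genes, however, 9 lay below 0 and 5 above, with Hrc at -1.08, Kcnd2 at -0.62 and Atp1b1 at 0.40. The 5 sarcomere genes therefore cannot decide this explanation. A dye bias as the whole cause would turn the sign between orientations, and the median was -0.0938 ± 0.0264 with Dil in Cy5 and -0.699 ± 0.0747 with Dil in Cy3. These errors are over genes and not over mice. The Cy3 value comes from set 4 alone. With the dye effect removed, the list medians were -0.18, -0.32, -0.31 and -0.50 in sets 1 to 4. Set 4 thus stayed the lowest set, against -0.699 on its direct array. How much of that Cy3 value goes back to the dye and how much to these mice is open. In Dil minus Hyp the list medians of the direct arrays were -0.113 with Dil in Cy5 and -0.286 with Dil in Cy3. No biological explanation was tested.

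Agt in Hyp3 lay close to WT3, at 0.22 on their own array after removal of the dye effect (before it, this ratio ran the other way, and 2 of 3 direct arrays had the fitted sign) and at 0.786 ± 1.06 through Dil3. A faulty spot on that array would leave the route through Dil3 within the other sets, whose lowest value was 2.24; the route lies below it by less than 2 standard errors, so this stays open. A WT mouse in place of Hyp3 would bring Nppb to WT level, and Nppb of Hyp3 over WT3 was 1.21 directly and 1.48 through Dil3 (1.81 and 1.75 standard errors), which leaves this open too. The weight index on the Hyp3 labels, 5.3 and 5.6 mg/g against at most 4.9 in WT, argues for a carrier, but it describes the label and not the RNA. The 2 routes use arrays whose Hyp3 labels differ and may hold different mice, and a difference in transgene expression was not tested.

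Single sets stood apart from the other 3 by a gap test in 11 of 131 groups of 4 values, and chance marks about 1 in 20 groups (6.55 here). For genes these were set 2 in Hyp minus WT for Chkb (-0.50, others -0.25 to -0.20) and Gpcpd1 (-0.61), set 3 in Dil minus WT for Ppp1r3c (0.82, others 1.17 to 1.23), set 4 in Dil minus WT for Kcnd2 (-1.04, others -0.51 to -0.42), and set 3 in Dil minus Hyp for Nabp1 (0.69). Among list medians they were calcium handling in Dil minus WT (-0.16, set 4), oxidative phosphorylation in Dil minus Hyp (-0.00109, set 1, others -0.30 to -0.28), glycolysis in Hyp minus WT (0.20, set 1), Notch pathway in Dil minus WT (-0.0346, set 3), ribosomal proteins in Dil minus Hyp (-0.51, set 2, others 0.03 to 0.13) and antioxidant genes in Hyp minus WT (-0.35, set 1, others 0.05 to 0.06).

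Control spots, left out of all tests, carried strong ratios. The highest mean of a position was 3.62 (2.56 to 4.68 over the arrays), and 10 of 23 positions had means above 1 in size.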

How the results depend on the processing

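Alternatives added after seeing the data are those on the order of the WT1 and Hyp1 array, on named spots alone and on the scaled dye term. In Hyp minus WT 0 features passed in every setting.

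Counts in Dil minus WT moved from 260 to 109 with arrays scaled to the same spread (60 higher, 49 lower), 7 from direct arrays alone, 6 with the replicate block and 159 with the WT1 and Hyp1 array left out. At adjusted p under 0.1 the count was 530. Leaving out a set gave 0 to 121.

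Counts in Dil minus Hyp moved from 20 to 43 without a dye term, 52 with arrays as independent, 0 from direct arrays alone and 0 with the replicate block. They were 41 with the WT1 and Hyp1 array as deposited, 7 with it left out, 37 over named spots alone and 64 at adjusted p under 0.1. Leaving out a set gave 0 to 15.

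Gene list calls fell from 20 to 0 with a correlation estimated by camera. They were 19 with the WT1 and Hyp1 array as deposited and 19 with it left out, both without the chaperone list in Dil minus Hyp (adjusted p = 0.245 and 0.0791). The correlation of Hyp minus WT with Dil minus WT was 0.395 from direct arrays alone against 0.684. No simulation without effects was run for direct arrays alone, and the 0.532 simulated for all 11 arrays is no measure for this value.

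The sign of 2 results that did not pass changed. Atp2a2 in Hyp minus WT, at 0.00 in the chosen fit, was -0.00200 with median centring, -0.0161 without a dye term, -0.0146 with arrays as independent, -0.0158 from direct arrays, -0.0299 with the WT1 and Hyp1 array as deposited, -0.0160 with it left out and -0.0110 with its last blocks also placed, and ran from -0.115 to 0.127 with a set left out. Agt in Dil minus Hyp was -0.228 with arrays scaled to the same spread and -0.0686 from direct arrays, and ran from -0.341 to 0.348 with a set left out. The 59 named gene results that passed kept their sign in every setting in which they had a value, 20 settings for 52 of them and 19 for 7.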

Other observations

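The tests of this part were chosen after the results were seen.

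4 gene lists outside the fixed ones were tested. Genes of protein translocation and glycosylation at the endoplasmic reticulum, listed after related genes (Sec11c, Ostc, Mpdu1, left out) had been seen, were higher in Hyp than in WT (median 0.12, 29 of 36 above 0, cameraPR adjusted p = 1.22e-10, adjusted p = 0.104 with an estimated correlation, 0 passing over all features or over the list alone). They were higher in Dil than in WT as well (median 0.10, 29 of 36 above 0, adjusted p = 0.00117, adjusted p = 0.149 with an estimated correlation) and did not pass in Dil minus Hyp (adjusted p = 0.394). In Dil minus WT, mitochondrial ribosomal protein genes were lower (median -0.15, 37 of 47 below 0, adjusted p = 1.39e-06, adjusted p = 0.113 with an estimated correlation), with Mrps35 (-0.51) and Mrps36 (-0.47) passing over all features and, adjusted over the list alone, 9 lower and 1 higher. Whether Mrps36 codes for a part of the mitochondrial ribosome was not checked here. Genes of branched-chain amino acid breakdown were also lower in Dil than in WT (median -0.23, 14 of 16 below 0, adjusted p = 1.63e-06, adjusted p = 0.104 with an estimated correlation), with Dbt (-0.70), Hsd17b10 (-0.53) and Mmut (-0.50) passing, and 6 lower over the list alone. Peroxisomal genes, without Abcd3 and Ech1, which had been seen, were lower (median -0.12, 17 of 20 below 0, adjusted p = 0.00222, adjusted p = 0.113 with an estimated correlation), with Pxmp2 (-0.65) passing and, over the list alone, 4 lower and 1 higher. In Hyp minus WT the peroxisomal (median -0.11, adjusted p = 0.00117), mitochondrial ribosomal (-0.05, adjusted p = 0.0149) and branched-chain lists (-0.08, adjusted p = 0.0131) were lower too, with adjusted p of 0.104, 0.305 and 0.263 with an estimated correlation. The sets were mixed, with peroxisomal medians of -0.27, 0.02, -0.11 and 0.02 and a mitochondrial ribosomal median of 0.06 in set 2. In Dil minus Hyp the mitochondrial ribosomal (adjusted p = 3.79e-06) and branched-chain lists (adjusted p = 9.42e-06) were lower and the peroxisomal list did not pass (adjusted p = 0.139), with adjusted p of 0.138, 0.104 and 0.540 with an estimated correlation.

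The sets differed in Dil minus Hyp, and not in the same way for every list. Correlations between sets over features ran from -0.293 (sets 1 and 2) to 0.574 (sets 3 and 4). The fatty acid oxidation median of Dil minus Hyp was -0.39 and -0.46 in sets 3 and 4 but 0.02 and 0.26 in sets 1 and 2. The oxidative phosphorylation median was -0.28, -0.28 and -0.30 in sets 2 to 4 and near 0 in set 1, and the chaperone median was -0.19, -0.13, -0.03 and -0.02 in sets 1 to 4.

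Agt lies in the last blocks and has no value on the WT1 and Hyp1 array in the chosen fit, so its printed changes rest on the other 10 arrays. The place on that array that matches Agt held 2.82, its deposited place held 0.02, and the other 2 arrays of set 1 summed to 3.47.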
